A study of Homo sapiens with 18 samples.

How the data were processed

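The study measured RNA in peripheral blood mononuclear cells (PBMC), the mixed lymphocytes, monocytes and dendritic cells of blood, from 2 donors. Cells were treated for 30 min with vehicle (DMSO) or with 5 µM BMS-986126, a small-molecule inhibitor of a kinase of the IRAK family, which relays Toll-like receptor signals through MyD88. Gardiquimod, a ligand of Toll-like receptor 7 (TLR7), was then added at 5 µg/ml for 5 h. The 3 conditions were unstimulated cells with vehicle, gardiquimod with vehicle, and gardiquimod with BMS-986126. Each condition was run in 3 wells of each donor, which gives 6 arrays per condition and 18 arrays in all. No well received BMS-986126 without gardiquimod.

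Each sample was hybridised to 1 Affymetrix Human Genome U219 array. The deposited values are log2 RMA values per probe set, background corrected, quantile normalised and summarised by the submitters, whose processing notes name RMA alone and no version. The log base is not written in the table and was taken from the scale that RMA gives and from the range of the values. The medians of the 18 arrays lay between 3.36 and 3.41. The table held no missing values and no detection calls. The number of arrays limits the precision of every value. The genome build of the probe annotation is not given in the sources used here, and no coordinates are therefore printed.

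The table held 49386 probe sets, of which 93 were array controls. The annotation gave a single gene for 45259 probe sets, and the gene number of 45178 of these probe sets was found in the reference gene table. A further 1327 probe sets matched several genes and 2713 had no gene in the annotation used, and both kinds were left out of the gene tests. Probe sets of Y-linked genes and of XIST (69) were left out of every test because the samples come from persons. The remaining probe sets covered 18211 genes, 6401 with 1 probe set and 11810 with 2 or more. A gene was represented by the probe set with the highest mean over the 18 arrays. Probe sets of one gene can disagree, and where another probe set of a named gene moved little or in the opposite direction this is stated beside the gene. The interferon-alpha genes are nearly identical in sequence, so the value of any single member is uncertain.

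Within a condition and donor the arrays correlated across genes at 0.9956 to 0.9974 (18 pairs). The same condition in the other donor gave 0.9867 to 0.9934 (27 pairs), and other conditions of the same donor gave 0.961 to 0.9951 (54 pairs). No array duplicated another. The principal components of the 18 arrays set unstimulated cells apart from both stimulated conditions on component 1 (63.2% of the variance). The donors also differed on it, so the stimulated conditions overlapped across donors but were separate within each donor. Component 2 (13.7%) separated the donors.

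Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with condition and donor as terms, on all 18 arrays, which share 1 estimate of the spread. The p-values were adjusted over the 18211 genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and the count at a change of at least 2-fold is given beside it. The verbs rose and fell are used only of called genes. All changes are log2 differences between conditions, given as estimate ± SE (n = 6 arrays per condition), and levels are means ± SD over the 6 arrays. The wells of a donor are replicates of that donor, and the donor term removes the difference in level between the donors. The p-values therefore measure the spread between wells of a donor, to which unequal responses of these 2 donors add. They do not measure the spread between persons. Differences between the donors' responses were tested with the interaction contrast of a fit to the 6 groups of condition and donor.

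Every donor is present in every condition, and the donor term carries this pairing. The wells also bear letters within a donor, and wells of the same letter in other conditions were checked for a closer relation after condition and donor had been removed. Their residual correlations had a median of 0.07 (range -0.161 to 0.249), and 7 of 18 pairs exceeded 0.1. Among pairs of wells with other letters 4 of 36 did so (range -0.243 to 0.19).

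The gene lists, the tests of the comparisons and the rule for named genes were fixed before the data were examined, while 5 tests of explanations in the closing section were chosen after the result was seen. The 30 lists comprised interferon-stimulated genes, interferon genes, interferon-gamma response genes, inflammatory cytokines, chemokines, NF-kB targets and feedback, immediate-early and MAPK feedback genes, the Toll-like receptor pathway, costimulation and dendritic cell maturation, and HLA class II presentation machinery. They further comprised glycolysis and hypoxia, cholesterol synthesis, aryl hydrocarbon receptor targets, NRF2 targets, metallothioneins, the unfolded protein response, heat shock genes, p53 and apoptosis genes, cell cycle genes, ribosomal proteins and glucocorticoid response genes. The last 9 were markers of monocytes, B cells, T cells, NK and cytotoxic cells, plasmacytoid dendritic cells, conventional dendritic cells, neutrophils, platelets and erythroid cells. Named genes were the 12 with the largest rise and the 12 with the largest fall (6 and 6 for gardiquimod with BMS-986126 against unstimulated) among called genes that changed at least 2-fold, in the same direction in both donors and with no overlap of the arrays within a donor. To these were added up to 4 called members of each list and 14 genes of the pathway whatever their result, of which 1 was not analysed here. HLA, immunoglobulin, T cell receptor and KIR genes, which vary between persons, were not named.

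Lists were tested with camera of limma at an inter-gene correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the data. Camera compares a list with the other genes, and the test of list scores described next does not. A list score, the mean log2 value of the list's measured members on an array, was compared between conditions by an exact two-sided permutation test within donor. Its 400 arrangements can give no p below 0.005, and these p-values were adjusted over the 30 lists as well. The score of the interferon-stimulated genes was compared with those of the inflammatory cytokines and of the NF-kB list by the same exact test.

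The reversal of the gardiquimod response by BMS-986126 was measured on genes that gardiquimod changed at least 2-fold. The remaining share is the log2 change from unstimulated with the compound as a percentage of that without it. Both comparisons use the gardiquimod arrays, which by itself makes their changes correlate negatively. The correlation was therefore also computed with separate gardiquimod arrays for the 2 comparisons. It was set beside 50 simulations of groups that neither gardiquimod nor the compound changed.

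The calculation was tested on simulated data with the same design and 18211 genes. At a true log2 change of 0.5, 97.0% of the changed genes were called for gardiquimod against unstimulated, 91.0% for the compound against gardiquimod and 94.0% for the compound against unstimulated. At a true change of 1 or 2 the share was 100%. Of the calls, 5.71%, 4.68% and 7.32% were false. A list shifted in the simulation was detected and 0 of 27 untouched lists were called. A remaining share of 60% was measured as 59.6%. A difference of 1 between the donors was detected in 190 of 200 genes, with 11 false calls. In the other steps the simulated effects were the same in both donors, and in all steps the genes varied independently. The shares found and the shares of false calls may therefore not carry over to the real arrays.

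A level under 3.06, the 40th percentile of all values, was taken as dim. The change of a gene that was dim in a condition may be understated. Alternatives of the values were a filter on dim probe sets, other choices of probe set, median centring and renewed quantile normalisation. Alternatives of the fit were no donor term, each donor alone, the means of the 2 donors as replicates and the 12 arrays compared alone. The replicate was also fitted as a fixed block in place of the donor term, and the parts of the array code as random blocks. Further alternatives were limma's trend and robust options, a test against a 1.5-fold change, the spread within condition and donor and the estimated correlation. Each array was also left out in turn. Data were read with the R package data.table (1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.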

Results

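Gene expression was measured on 18 arrays of peripheral blood mononuclear cells (PBMC) from 2 donors, in 3 conditions with 6 arrays each (3 wells per donor). The cells were unstimulated, stimulated for 5 h with gardiquimod, a ligand of the endosomal receptor TLR7, or stimulated after 30 min with BMS-986126, an inhibitor of a kinase of the IRAK family that acts downstream of MyD88. Values are RMA values on the log2 scale, and 18211 genes were tested with limma. Wells of the same donor serve as replicates, so the adjusted p-values speak for the spread between wells, to which unequal responses of these 2 donors add. They do not speak for the spread between persons. The number of arrays limits the precision.

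The response to the TLR7 ligand was measured by comparing gardiquimod with unstimulated cells, both with vehicle. Gardiquimod raised all 48 measured interferon-stimulated genes, 12 of 26 chemokines and 17 of 29 inflammatory cytokines, and 6 genes of each of the last 2 lists fell. CXCL11, a chemokine that attracts activated T cells, rose 248-fold, from 3.67 ± 0.58 to 11.62 ± 0.40 (SD, n = 6), a log2 change of 7.95 ± 0.15 (adjusted p = 2.9e-20). RSAD2, which encodes the antiviral protein viperin, rose 245-fold, from 4.36 ± 0.68 to 12.29 ± 0.18 (adjusted p = 5.71e-19). The monocyte chemokine CCL2 rose by 7.74 ± 0.12. Among the largest falls were those of the complement receptor C5AR1, which fell 8.33-fold, and of the thrombin receptor thrombomodulin (THBD), which fell 15.7-fold.

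**Figure D1:**
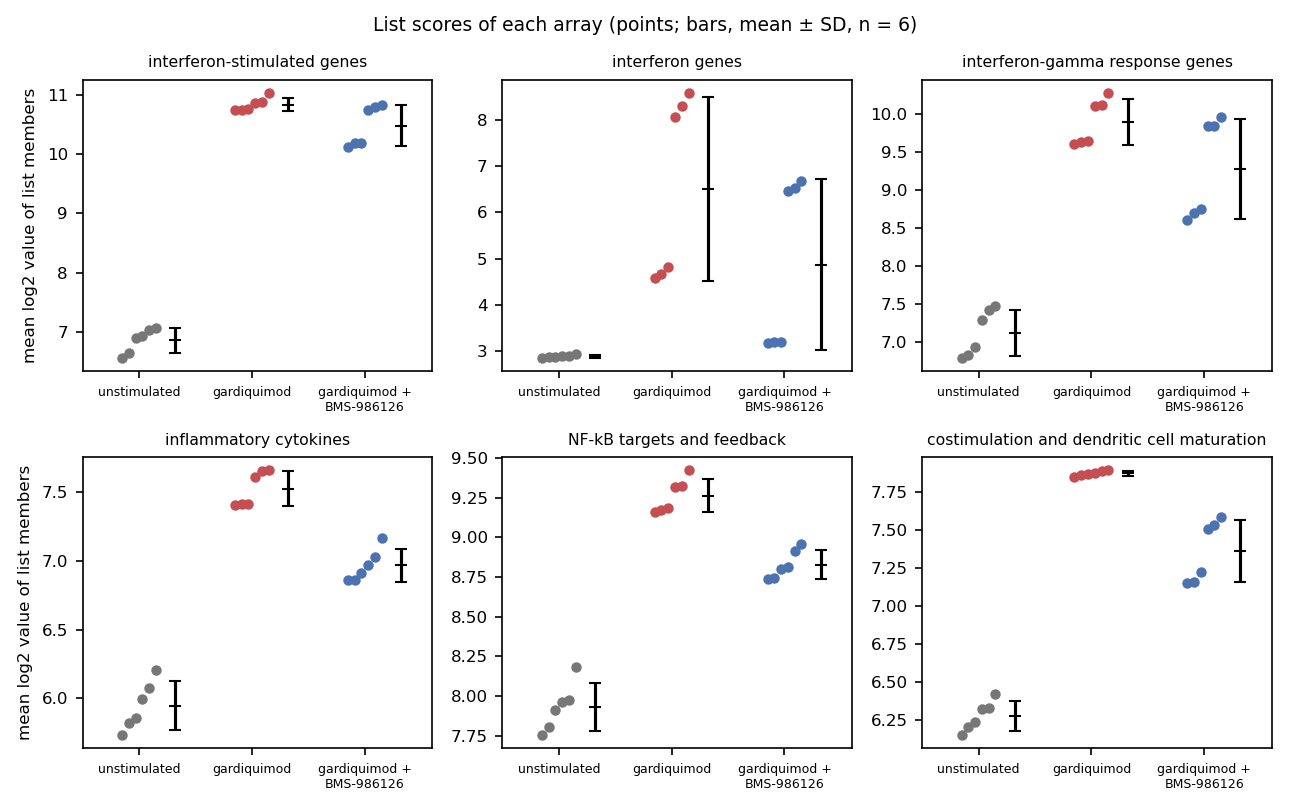
List scores per array for 6 gene lists: each point is the mean log2 value of the measured list members on 1 array, grouped on the horizontal axis by condition, and the bars are mean ± SD of 6 arrays. The score of the interferon-stimulated genes was higher than unstimulated by 3.98 with gardiquimod and by 3.62 with gardiquimod and BMS-986126.

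All 48 measured interferon-stimulated genes rose, and the count adjusted over the list alone was also 48. Their median change was 4.10 and their mean 3.98 ± 0.07 (camera adjusted p = 5.52e-72, adjusted p = 0.0027 with an estimated correlation). Besides RSAD2, the largest changes belonged to the antiviral genes IFIT1 (6.71) and IFIT3 (6.63) and to USP18 (6.62), which restrains interferon receptor signalling. ISG15, a ubiquitin-like protein, rose by 4.55 ± 0.13 (23.5-fold) and the dynamin-like antiviral MX1 by 4.67 ± 0.08 (25.4-fold). All 15 measured interferon genes rose (15 adjusted over the list alone), with a mean change of 3.61 ± 0.51 (camera adjusted p = 1.01e-10, adjusted p = 0.156 with an estimated correlation). Their score was higher by 5.43 in one donor and by 1.79 in the other. IFNB1, the gene of interferon-beta, rose by 4.34 ± 0.50 (20.3-fold, adjusted p = 2.74e-07) and IFNA5 by 6.14 ± 0.65. Both were below the dim level of 3.06 in unstimulated cells, and probes of the interferon-alpha genes may also bind other members of the family. Of 28 interferon-gamma response genes 27 rose, 0 fell and 1 was not called (27 adjusted over the list alone). Their mean was 2.78 ± 0.10 (camera adjusted p = 1.91e-32, adjusted p = 0.0106 with an estimated correlation). They included IDO1, which degrades tryptophan (6.34), ANKRD22 (5.74 ± 0.25) and the chemokine CXCL10 (5.44 ± 0.32, 43.4-fold).

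Among 29 inflammatory cytokines 17 rose, 6 fell and 6 were not called (17 and 7 adjusted over the list alone). Their mean change was 1.58 ± 0.08 (camera adjusted p = 6.54e-09, adjusted p = 0.0106 with an estimated correlation). IL6 rose by 6.25 ± 0.42, IL12B, which encodes the shared subunit of IL-12 and IL-23, by 5.96 ± 0.16 (62.4-fold), and IL27 by 4.81 ± 0.30 (28.1-fold). IL12B was dim in unstimulated cells, so its rise may be understated. TNF rose 10.4-fold (3.38 ± 0.18) and IL1B 4.48-fold (2.16 ± 0.20). Of 26 chemokines 12 rose, 6 fell and 8 were not called (12 and 7 adjusted over the list alone). Their median was 0.18 and their mean 1.47 ± 0.07 (camera adjusted p = 0.000217, adjusted p = 0.0467 with an estimated correlation). The monocyte attractants CCL8 (7.71 ± 0.17) and CCL7 (6.51) rose, while the neutrophil attractants CXCL2 and CXCL3 had changes of -3.17 ± 0.27 and -3.13 ± 0.39 and thus fell.

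Of 38 NF-kB targets and feedback genes 28 rose, 4 fell and 6 were not called (31 and 4 adjusted over the list alone). Their mean was 1.33 ± 0.06 (camera adjusted p = 2.22e-20, adjusted p = 0.0166 with an estimated correlation). The A20-binding protein TNIP3 rose 53.4-fold, the soluble pattern receptor PTX3 46.3-fold and the inhibitor of NF-kB NFKBIA 1.88-fold. One of the TNIP3 probe sets changed by only 0.20. Of 25 genes of costimulation and dendritic cell maturation 21 rose, 2 fell and 2 were not called, the same counts as when adjusted over the list alone. Their mean was 1.59 ± 0.07 (camera adjusted p = 3.52e-15, adjusted p = 0.0106 with an estimated correlation). LAMP3, a lysosomal protein of mature dendritic cells, rose by 5.45 ± 0.28, the costimulatory ligand CD80 by 4.83 ± 0.14 and IL15RA, which presents IL-15, by 4.69 ± 0.14. In the Toll-like receptor pathway 16 of 38 genes rose, 10 fell and 12 were not called (17 and 13 adjusted over the list alone). Its median was -0.02, whereas its mean was 0.44 ± 0.03 and camera placed it higher (adjusted p = 0.00522, adjusted p = 0.0428 with an estimated correlation). TLR7 itself rose 19.2-fold (4.26 ± 0.18), its relative TLR8 10.5-fold, and UNC93B1, which carries both receptors to endosomes, 3.46-fold. The adaptor MYD88 rose 2.13-fold, although another of its probe sets changed by -0.01, and the kinase IRAK1 fell by 1.55 ± 0.10.

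Immediate-early and MAPK feedback genes went in both directions: 10 of 35 rose, 16 fell and 9 were not called (10 and 16 adjusted over the list alone). Their median was -0.18, their mean -0.03 ± 0.03 and camera gave the direction up (adjusted p = 0.93). DUSP5, a phosphatase of ERK, rose by 3.22 ± 0.15 and the transcription factor MYC by 1.61 ± 0.11, and the phosphatase DUSP10 fell by 1.40 ± 0.12. Of 8 metallothioneins, which bind zinc and copper, 6 rose and 2 were not called (7 adjusted over the list alone), and MT2A rose 4.83-fold. Their mean was 0.79 ± 0.05 (camera adjusted p = 2.89e-05, adjusted p = 0.0169 with an estimated correlation). Of 17 p53 and apoptosis genes 8 rose, 5 fell and 4 were not called (9 and 5 adjusted over the list alone). Their mean was 0.34 ± 0.02 (camera adjusted p = 0.0145, adjusted p = 0.0617 with an estimated correlation). The death receptor FAS rose 4.58-fold and the BH3-only gene PMAIP1 by 1.31 ± 0.08, while BBC3, of the same class, fell by 0.99 ± 0.09.

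Lists of metabolism and stress held members that rose and members that fell, and camera called none of them. In glycolysis and hypoxia 6 of 24 rose, 11 fell and 7 were not called (8 and 11 adjusted over the list alone), with a median of 0.02, a mean of -0.13 ± 0.03 and a camera direction of up (adjusted p = 0.93). The aldolase ALDOC fell by 1.54 ± 0.09 and the glucose transporter SLC2A1 by 0.97 ± 0.08. In the unfolded protein response 6 of 19 rose, 6 fell and 7 were not called, as also when adjusted over the list alone (median 0.04, mean -0.22 ± 0.04, camera up, adjusted p = 0.89). Its stress-induced members TRIB3 (5.42-fold), SESN2 and DDIT3 fell. Cholesterol synthesis had 3 of 17 members up, 6 down and 8 not called (mean -0.07 ± 0.03, camera up, adjusted p = 0.93), and EBP fell by 0.75 ± 0.11. NRF2 targets had 2 of 11 up, 3 down and 6 not called (2 and 4 adjusted over the list alone, camera adjusted p = 0.89), and the cystine transporter SLC7A11 fell by 1.47 ± 0.15. Of 7 aryl hydrocarbon receptor targets 2 rose, 1 fell and 4 were not called (2 and 2 adjusted over the list alone, camera adjusted p = 0.49). These were TIPARP (1.05 ± 0.07), AHRR (0.96 ± 0.14) and the monooxygenase CYP1B1, which fell by 1.45 ± 0.15. Heat shock genes had 1 of 12 up (the co-chaperone DNAJA1, 1.56 ± 0.07), 5 down and 6 not called, with a median of -0.10, a mean of 0.03 ± 0.04 and camera up (adjusted p = 0.93). HLA class II presentation machinery had 3 of 10 up, 3 down and 4 not called (median -0.05, mean -0.05 ± 0.03, camera up, adjusted p = 0.89), cell cycle genes 3 of 24 up, 4 down and 17 not called (median -0.02, mean -0.01 ± 0.02, camera up, adjusted p = 0.89). Ribosomal protein genes had 0 of 28 up, 12 down and 16 not called (mean -0.12 ± 0.02, camera adjusted p = 0.0732). Glucocorticoid response genes had 3 of 12 up, 5 down and 4 not called (mean -0.26 ± 0.05, camera adjusted p = 0.89), with the decoy receptor IL1R2 up by 2.81 ± 0.14 and ERRFI1 down, at -1.85 ± 0.09. For these last lists, and for heat shock genes and cholesterol synthesis, the counts adjusted over the list alone were the same.

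Camera called none of the 9 lists of blood cell markers, and 7 of them held both members that rose and members that fell. Of 18 monocyte markers 6 rose, 7 fell and 5 were not called (6 and 8 adjusted over the list alone), with a median of -0.02 and a mean of 0.26 ± 0.05 (camera up, adjusted p = 0.337). The scavenger receptor CD163 rose 5.65-fold and the nuclear antigen MNDA 5.09-fold. Of 13 B cell markers 3 rose, 6 fell and 4 were not called (mean -0.33 ± 0.02, camera adjusted p = 0.525). CD79B, part of the B cell receptor, fell 4.7-fold on the probe set used, and its other probe sets changed by -0.17 to -0.04. Of 16 T cell markers 2 rose, 8 fell and 6 were not called (mean -0.21 ± 0.02, camera adjusted p = 0.329), with CD3G and the kinase LCK down by log2 changes of -0.85 ± 0.08 and -0.81 ± 0.07. NK and cytotoxic cell markers had 5 of 18 up, 7 down and 6 not called (mean -0.03 ± 0.03, camera adjusted p = 0.93), with perforin (PRF1) up by 1.40 ± 0.13. Plasmacytoid dendritic cell markers had 4 of 12 up, 3 down and 5 not called (5 and 3 adjusted over the list alone, mean 0.19 ± 0.03, camera adjusted p = 0.259). Conventional dendritic cell markers had 1 of 10 up, 3 down and 6 not called (median -0.13, mean 0.02 ± 0.04, camera down, adjusted p = 0.89), where the transcription factor BATF3 rose 12.1-fold and the lectin CLEC10A fell 5.86-fold. Neutrophil markers had 0 of 16 up and 3 down (mean -0.06 ± 0.03, camera adjusted p = 0.936), platelet markers 1 of 12 up and 2 down (mean -0.07 ± 0.03, camera adjusted p = 0.93) and erythroid markers 0 of 8 called (median -0.11, mean -0.08 ± 0.13, camera up, adjusted p = 0.93). Where no other count is given for a marker list, that adjusted over the list alone was the same. The difference between 3' and 5' control probe sets, a measure of RNA integrity, moved with gardiquimod by -0.171 for beta-actin, from 0.946 ± 0.109 to 0.775 ± 0.0765 (SD, n = 6, two-sided exact permutation p = 0.005), and by 0.0202 for GAPDH (two-sided exact permutation p = 0.415).

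Outside the lists, leptin (LEP) had the largest fall, from 8.81 ± 0.18 to 3.42 ± 0.47, and another of its probe sets changed by -2.22. NLRP12, an inhibitory sensor of myeloid cells, fell by 3.64 ± 0.20 and the interleukin-1 receptor IL1R1 by 3.52 ± 0.17. The median change with gardiquimod was -0.03 over all genes and -0.112 over the 12626 genes left by the filter on dim probe sets. In all, 7098 genes were called, 2117 higher and 4981 lower (29.8% higher). At 2-fold or more, 653 were higher and 320 lower, and 971 of these 973 had no overlap of arrays within either donor. Camera called 10 lists up and 0 down, of which 8 kept the call with the estimated correlation. The exact permutation test of the list scores, which does not compare a list with the other genes, called 21 of 30 lists. Its calls therefore do not show a shift particular to a list. The smallest possible p of this test, 0.005, gave an adjusted p of 0.00833 for all lists that camera called. NRF2 targets, the unfolded protein response, ribosomal protein genes and glucocorticoid response genes, not called by camera, had the same adjusted p. So had the markers of monocytes, B cells, T cells and plasmacytoid dendritic cells. Glycolysis and hypoxia, neutrophil markers (both 0.015) and aryl hydrocarbon receptor targets (0.0214) were called by the exact test as well.

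The second comparison, gardiquimod with BMS-986126 against gardiquimod with vehicle, asked what the inhibitor changed in stimulated cells. IL12B, at 8.79 ± 0.67 with gardiquimod, was at 5.63 ± 0.50 with the compound, 8.92-fold lower (-3.16 ± 0.16, adjusted p = 2.74e-11). The anti-inflammatory cytokine IL10 was 5.46-fold lower (-2.45 ± 0.10, adjusted p = 1.43e-12) and the succinate receptor SUCNR1 9.56-fold lower (-3.26 ± 0.18, adjusted p = 4.54e-11). ISG15 and MX1 were at 12.74 ± 0.27 and 12.24 ± 0.13 with the compound, against 12.77 ± 0.12 and 12.41 ± 0.09 without it, and neither was called. CYP1B1, a monooxygenase induced by the aryl hydrocarbon receptor, rose 11.4-fold, from 5.17 ± 0.40 to 8.68 ± 0.14 (adjusted p = 1.43e-12).

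**Figure D2:**
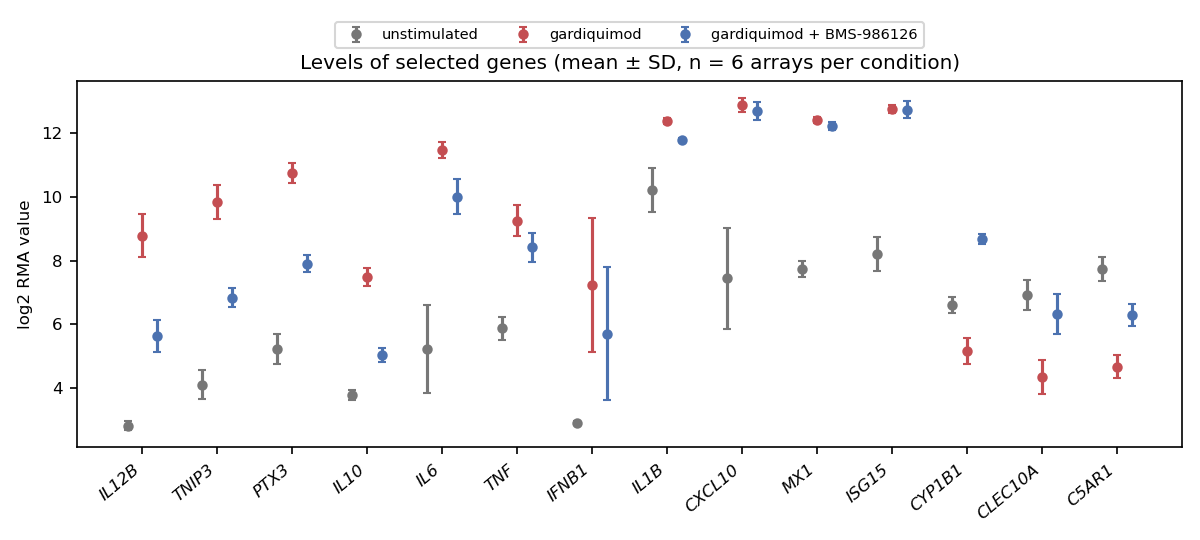
Levels of 14 named genes: genes are on the horizontal axis and log2 RMA values on the vertical axis, with a coloured point for the mean of each condition and bars for the SD of 6 arrays. With BMS-986126 IL12B lay between its levels in unstimulated and gardiquimod-treated cells (2.82, 8.79 and 5.63 in unstimulated, gardiquimod and compound), whereas ISG15 stayed near its gardiquimod level (12.77 and 12.74). ISG15 lay near the top of the range of the arrays, where a loss may be hidden.

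Of 29 inflammatory cytokines 13 fell with the compound, 3 rose and 13 were not called (16 and 3 adjusted over the list alone), with a mean change of -0.56 ± 0.08. Camera called the list lower (adjusted p = 7.34e-08), and it was the 1 list that kept its call with the estimated correlation (adjusted p = 0.0454). Besides IL12B and IL10, EBI3, the partner subunit of IL-27, fell 3.15-fold. TNF fell by 0.84 ± 0.18 and IL6 by 1.47 ± 0.42, although neither was called when the 2 donor means served as replicates, nor IL6 with limma's trend and robust options. IL1B changed by -0.59 ± 0.20 at an adjusted p of 0.049, and leaving out any 1 of the 12 arrays compared ended that call (adjusted p = 0.0597 to 0.0961). Of 38 NF-kB genes 22 fell, 3 rose and 13 were not called (24 and 5 adjusted over the list alone), with a mean of -0.43 ± 0.06 (camera adjusted p = 1.21e-09, adjusted p = 0.119 with an estimated correlation). TNIP3 was 8.03-fold lower (-0.09 on another probe set), PTX3 7.22-fold lower, the cyclooxygenase PTGS2 2.96-fold lower and SOCS3, which restrains cytokine receptors, 2.86-fold lower. NFKBIA changed by -0.28 ± 0.07, a call that was lost with donor means. Of 25 costimulation and maturation genes 14 fell, 2 rose and 9 were not called (17 and 2 adjusted over the list alone), with a mean of -0.51 ± 0.07 (camera adjusted p = 1.24e-08, adjusted p = 0.0885 with an estimated correlation). The score of this list changed by -0.70 in one donor and by -0.32 in the other. The ligand TNFSF9 was 2.86-fold lower and SLAMF1 2.64-fold lower. Of 26 chemokines 8 fell, 3 rose and 15 were not called (12 and 6 adjusted over the list alone), with a mean of -0.18 ± 0.07 (camera adjusted p = 0.0242, adjusted p = 0.183 with an estimated correlation). CCL19, a ligand of CCR7, was 3.19-fold lower and below the dim level with the compound, and CXCL2 rose by 1.39 ± 0.27, a call that was lost with donor means.

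Of 48 interferon-stimulated genes 26 fell, 0 rose and 22 were not called (30 lower adjusted over the list alone). Their mean change was -0.36 ± 0.07 (camera adjusted p = 2.25e-14, adjusted p = 0.121 with an estimated correlation). LGALS3BP fell by 0.71 ± 0.11, and ISG15 and MX1 had changes of -0.02 ± 0.13 and -0.17 ± 0.08. IFI27 fell by 1.45 ± 0.22, a call that was lost with donor means. Of 15 interferon genes 9 fell and 6 were not called (15 lower adjusted over the list alone), with a mean of -1.63 ± 0.51 (camera adjusted p = 8.83e-09, adjusted p = 0.166 with an estimated correlation). Their score changed by -1.8 and -1.5 in the donors, and the SE of 0.51 also holds the donors' unequal rise with gardiquimod. IFNB1 changed by -1.53 ± 0.50 (adjusted p = 0.0404). Its call was lost with the replicate as a fixed block (adjusted p = 0.0783), with donor means and without the donor term. It was also lost with limma's trend and robust options and with the mean of each gene's probe sets. Leaving out any 1 of 6 single arrays ended it too (adjusted p = 0.0773 to 0.104). The calls of IFNA5, IFNA10 and IFNA17 were lost with donor means as well. Of 28 interferon-gamma response genes 20 fell and 8 were not called (22 adjusted over the list alone), with a mean of -0.62 ± 0.10 (camera adjusted p = 5.82e-15, adjusted p = 0.0885 with an estimated correlation). The signalling suppressor SOCS1 fell 2.49-fold, and CXCL10 had a change of -0.20 ± 0.32 (adjusted p = 0.771).

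No difference was detected between the interferon-stimulated genes and the inflammatory cytokines in the change of their scores with the compound (0.20, two-sided exact permutation p = 0.095, adjusted 0.127; donors -0.05 and 0.45). Nor was one detected against the NF-kB list (0.08, two-sided exact permutation p = 0.385; donors -0.17 and 0.32). With gardiquimod alone the interferon-stimulated genes had risen more than the cytokines by 2.40 and more than the NF-kB list by 2.65 (exact permutation p = 0.005 for both, the smallest it can give). These scores include list members that gardiquimod did not raise.

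In the Toll-like receptor pathway 6 of 38 genes rose with the compound, 9 fell and 23 were not called (7 and 10 adjusted over the list alone; median 0.05, mean -0.04 ± 0.03, camera down, adjusted p = 0.826). TLR8 was 3.07-fold lower, while MYD88 was at 0.01 ± 0.07. TLR7 fell by 1.05 ± 0.18 and IRAK1 rose by 0.51 ± 0.10, both calls that were lost with donor means. Immediate-early and MAPK feedback genes had 8 of 35 up, 11 down and 16 not called (8 and 12 adjusted over the list alone, mean 0.01 ± 0.03, camera down, adjusted p = 0.646), with the phosphatase DUSP6 up by 0.81 ± 0.11. In glycolysis and hypoxia 11 of 24 genes fell, 0 rose and 13 were not called, as when adjusted over the list alone (mean -0.20 ± 0.03, camera adjusted p = 1e-07, adjusted p = 0.0885 with an estimated correlation), among them the phosphofructokinase PFKP (-0.65 ± 0.08). Metallothioneins had 4 of 8 down and 4 not called (mean -0.19 ± 0.05, camera adjusted p = 0.0199, adjusted p = 0.166 with an estimated correlation). Glucocorticoid response genes had 2 of 12 up, 5 down and 5 not called (3 and 6 adjusted over the list alone). Their mean was -0.17 ± 0.05 (camera adjusted p = 0.0242, adjusted p = 0.0885 with an estimated correlation), and the co-chaperone FKBP5 fell by 0.69 ± 0.07. Camera did not call p53 and apoptosis genes (4 of 17 up, 5 down, 8 not called, 6 and 7 adjusted over the list alone, adjusted p = 0.152), where BCL2A1, an anti-apoptotic gene, fell by 0.84 ± 0.08. It called neither HLA class II machinery (1 of 10 up, 1 down, 8 not called, median 0.02, mean 0.00, camera down, adjusted p = 0.826) nor cell cycle genes (2 of 24 up, 2 down, 20 not called, 3 and 2 adjusted over the list alone, adjusted p = 0.551).

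Of 7 aryl hydrocarbon receptor targets 3 rose, 0 fell and 4 were not called, as when adjusted over the list alone. The median was 0.15 and the mean 0.68 ± 0.05 (camera up, adjusted p = 0.0112, adjusted p = 0.0885 with an estimated correlation). Besides CYP1B1 these were AHRR, the receptor's repressor (0.81 ± 0.14), and CYP1A1 (0.34 ± 0.09), which was below the dim level in all 3 conditions and had another probe set of opposite sign. Both calls were lost with donor means. CYP1B1 had another probe set at 0.15. Heat shock genes had 5 of 12 up and 7 not called (mean 0.16 ± 0.04, camera adjusted p = 0.0242, adjusted p = 0.284 with an estimated correlation), and ribosomal protein genes 5 of 28 up and 23 not called (6 adjusted over the list alone, mean 0.10 ± 0.02, camera adjusted p = 0.000872, adjusted p = 0.166 with an estimated correlation). NRF2 targets had 4 of 11 up, 2 down and 5 not called (5 and 3 adjusted over the list alone, camera adjusted p = 0.177), with the sulfiredoxin SRXN1 up by 0.78 ± 0.11. Cholesterol synthesis had 5 of 17 up, 2 down and 10 not called (7 and 3 adjusted over the list alone, camera adjusted p = 0.468), with EBP up by 0.70 ± 0.11. The unfolded protein response had 7 of 19 up, 4 down and 8 not called (camera adjusted p = 0.551).

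Among cell markers, 5 of 16 T cell markers rose, 3 fell and 8 were not called (6 and 3 adjusted over the list alone), with a mean of 0.16 ± 0.02 (camera adjusted p = 0.0242, adjusted p = 0.166 with an estimated correlation), and LCK rose by 0.75 ± 0.07. Of 13 B cell markers 4 rose, 1 fell and 8 were not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.119), among them TCL1A (0.75 ± 0.08). NK and cytotoxic markers had 9 of 18 up, 3 down and 6 not called (10 and 3 adjusted over the list alone, camera adjusted p = 0.0776). Monocyte markers had 3 of 18 up, 6 down and 9 not called (5 and 8 adjusted over the list alone, mean -0.08 ± 0.05, camera adjusted p = 0.401), with the chemokine receptor CCR2 at -0.83 ± 0.09. Conventional dendritic cell markers had 2 of 10 up and 1 down (camera adjusted p = 0.669), of which CLEC10A rose 3.9-fold. Plasmacytoid dendritic cell markers had 2 of 12 up and 1 down (camera adjusted p = 0.826), neutrophil markers 4 of 16 up (camera adjusted p = 0.0532), platelet markers 5 of 12 up and 1 down (camera adjusted p = 0.119) and erythroid markers 0 of 8 called (camera adjusted p = 0.481). Where no other count is given for a list in this comparison, that adjusted over the list alone was the same. The 3' to 5' difference moved with the compound by 0.142 for beta-actin (0.134 and 0.151 in the donors, two-sided exact permutation p = 0.03) and by 0.0183 for GAPDH (two-sided exact permutation p = 0.465).

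Outside the lists the detoxifying transferase MGST1 rose 4.18-fold, GAS7 by 1.98 ± 0.09 and the matrix protein thrombospondin (THBS1) 2.77-fold. C5AR1 rose 3.07-fold, with another probe set at 0.12. FSD1L was 9.29-fold lower and the carboxypeptidase CPM 6.52-fold lower. In all, 3112 genes were called, 1778 higher and 1334 lower, with a median change of all genes of 0.01. At 2-fold or more 43 were higher and 133 lower, and 173 of these 176 had no overlap of arrays within either donor. With the 2 donor means as replicates the count was 489 genes, 243 higher and 246 lower. Camera called 4 lists up and 10 down, of which 0 up and 1 down kept the call with the estimated correlation. The exact permutation test of the scores called 21 of 30 (adjusted p = 0.0107 for the cytokine, NF-kB, costimulation, chemokine and 3 interferon lists).

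Of the 653 genes that rose at least 2-fold, 465 fell with BMS-986126, 123 of them at least 2-fold, 4 rose and 184 were not called (71.2% lowered). With one donor alone 35.4% of the risen genes were lowered. Compared with unstimulated cells, 626 of the 653 were still called. The median remaining share of the rise was 72% (interquartile range 55.6 to 85.4%; donors 57.4 and 85.5%). Of the 320 genes that fell at least 2-fold, 216 rose with the compound, 36 of them at least 2-fold, 4 fell further and 100 were not called (38.1% raised with that donor alone), with a median remaining share of 68.0% (interquartile range 49.4 to 80.3%; donors 53.5 and 80.1%).

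**Figure D3:**
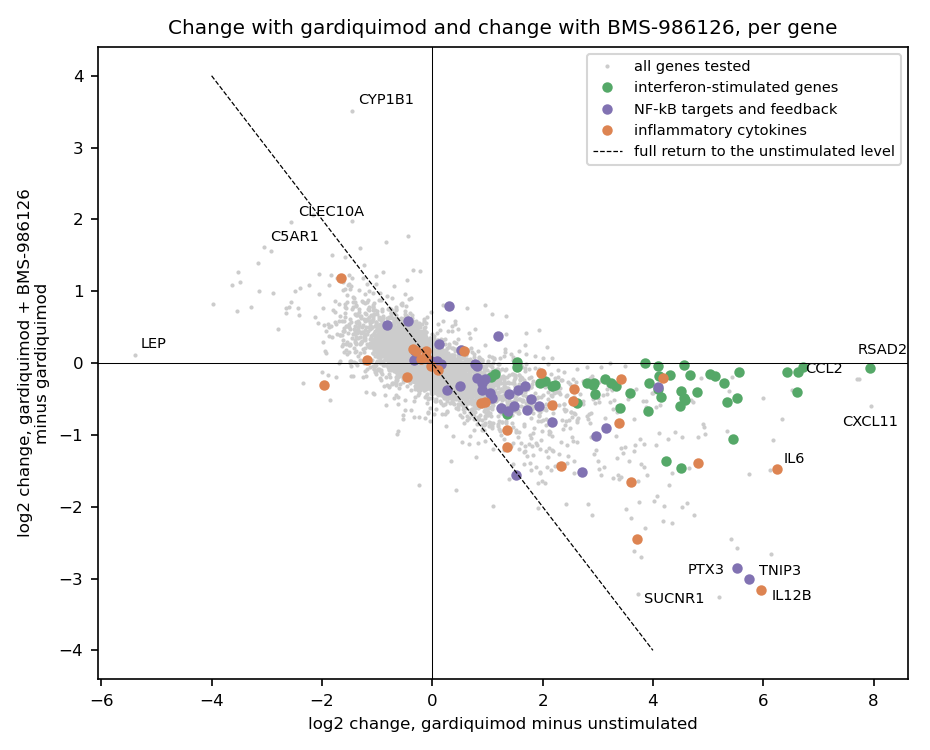
Each point is 1 gene: the horizontal axis is the log2 change with gardiquimod and the vertical axis the log2 change with BMS-986126 added to gardiquimod, with colours for 3 gene lists and a dashed line for full return to the unstimulated level. IL12B lies at 5.96 and -3.16, and RSAD2 at 7.94 on the horizontal axis close to 0 on the vertical one.

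Among all called genes, 1018 rose with gardiquimod and fell with the compound where 155 were expected by chance, and 1547 fell and then rose where 486 were expected. These overlaps, like the correlation of the changes across genes (-0.696), rest on shared gardiquimod arrays, and genes are not independent replicates. Simulated data without an effect of gardiquimod or of the compound gave a correlation of -0.498. The covariance of the changes was -0.107 in the data and -0.00396 in that simulation. The simulated correlation therefore does not measure how much of -0.696 comes from sharing. With separate gardiquimod arrays for the 2 comparisons the correlation was -0.677 and -0.602.

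**Figure D4:**
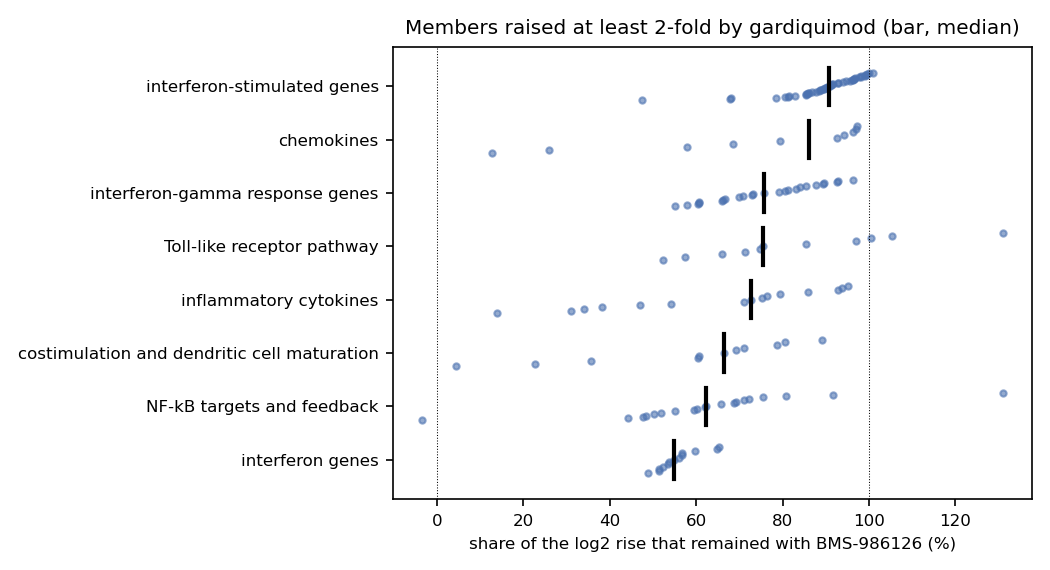
Share of the gardiquimod rise that remained with BMS-986126, in percent of the log2 change, for genes that gardiquimod raised at least 2-fold, by gene list; points are genes, bars mark the medians, and dotted lines stand at 0 and 100%. The median was 90.8% for interferon-stimulated genes and 62.2% for NF-kB targets and feedback.

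The median share of the rise that remained is described for each list, and differences of this share between lists were not tested across arrays. Over the 2 donors together it was 90.8% (interquartile range 86.1 to 96.4%) for the 48 interferon-stimulated genes, 86.0% for 10 chemokines, 75.8% for 25 interferon-gamma response genes and 75.4% for 11 genes of the Toll-like receptor pathway. It was 72.8% for 15 inflammatory cytokines, with the wide range of 42.6 to 82.7%, 66.5% for 11 costimulation genes, 62.2% for 20 NF-kB genes (51.5 to 71.4%) and 54.9% for 13 interferon genes. The share of the interferon genes differed widely between the donors: their score stood 5.43 above unstimulated with gardiquimod and 3.67 with the compound in one donor, and 1.79 and 0.29 in the other. The interferon genes named above were also below the dim level in unstimulated cells. The 48 interferon-stimulated genes exceeded the 35 cytokine and NF-kB genes together by 25.1 points (95% bootstrap interval 17.6 to 36.1), and by 28.6 and 24.7 points in the donors. That interval covers the choice of genes, not the spread between arrays.

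The last comparison, gardiquimod with BMS-986126 against unstimulated cells, shows what remained of the response, with stimulus and compound both differing. All 48 interferon-stimulated genes stayed above unstimulated cells (mean 3.62 ± 0.07, camera adjusted p = 4.37e-94; 48 adjusted over the list alone). RSAD2 was 233-fold higher, CCL2 183-fold, CXCL11 164-fold and IFIT3 90.6-fold. IL6 was 27.5-fold, IL12B 7-fold and TNF 5.82-fold higher. CYP1B1 was above both other conditions, 4.17-fold higher than in unstimulated cells (2.06 ± 0.15, adjusted p = 2.78e-10). LEP and THBD remained lower, at -5.28 ± 0.21 and -3.15 ± 0.28.

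Interferon genes had 13 of 15 higher (mean 1.98 ± 0.51, camera adjusted p = 5.14e-07, adjusted p = 0.247 with an estimated correlation). Their score was 3.67 above unstimulated in one donor and 0.29 in the other (adjusted p of the difference = 3.06e-12). Interferon-gamma response genes had 27 of 28 higher (mean 2.16 ± 0.10). Of the inflammatory cytokines 15 were higher, 3 lower and 11 not called (16 and 5 adjusted over the list alone, mean 1.02 ± 0.08), and of the NF-kB genes 28, 2 and 8 (30 and 2 adjusted over the list alone, mean 0.90 ± 0.06). Chemokines had 8 higher, 6 lower and 12 not called (mean 1.29 ± 0.07, camera adjusted p = 0.00117, adjusted p = 0.0725 with an estimated correlation). Costimulation genes had 17 higher and 1 lower (mean 1.08 ± 0.07), the Toll-like receptor pathway 15 higher, 10 lower and 13 not called (15 and 11 adjusted over the list alone, mean 0.39 ± 0.03). Metallothioneins had 6 of 8 higher (camera adjusted p = 7.89e-05) and aryl hydrocarbon receptor targets 4 of 7 (mean 0.75 ± 0.05, camera adjusted p = 0.000236). Glycolysis and hypoxia had 2 of 24 higher, 13 lower and 9 not called (mean -0.34 ± 0.03, camera adjusted p = 0.00123, adjusted p = 0.21 with an estimated correlation), with ALDOC at -1.42 ± 0.09. Heat shock genes had 2 of 12 higher (camera adjusted p = 0.0226, adjusted p = 0.305 with an estimated correlation) and p53 and apoptosis genes 7 of 17 higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.00629, adjusted p = 0.0423 with an estimated correlation). The other 17 lists were not called. Among them the immediate-early genes, HLA class II machinery, NRF2 targets, the unfolded protein response and ribosomal protein genes had a negative median and mean but the camera direction up, and conventional dendritic cell markers had a median of -0.03 and a mean of 0.04 ± 0.04. In all, 5504 genes were called, 1606 higher and 3898 lower, and 590 at 2-fold or more, 429 higher and 161 lower. With donor means as replicates the count was 3119. The 3' to 5' difference moved by 0.0385 for GAPDH (two-sided exact permutation p = 0.04) and by -0.0285 for beta-actin (two-sided exact permutation p = 0.635).

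The donors' changes correlated across genes at 0.917 for gardiquimod against unstimulated, 0.619 for the compound against gardiquimod and 0.872 for the compound against unstimulated, and genes are not independent replicates. The interaction test called 241, 435 and 562 genes in the 3 comparisons. The interferon genes rose with gardiquimod by 5.43 in one donor and 1.79 in the other. With the compound the interferon-gamma response genes changed by -0.95 in one donor and -0.29 in the other (adjusted p of the difference = 2.3e-05), and the interferon-stimulated genes by -0.58 and -0.13 (adjusted p of the difference = 0.0017). No characteristic of the donors was used.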

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

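The test of the remaining share in pairs of genes with like rises, the tests of a return from the gardiquimod fall and of aryl hydrocarbon receptor targets for CYP1B1, and both tests of the difference between donors, were chosen only after the result was seen.

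Interferon-stimulated genes kept more of their rise with BMS-986126 than cytokines and NF-kB targets did, by 25.1 points of the median remaining share. Near saturation of the arrays may hide a loss, but among members below log2 11 with gardiquimod the difference was 34.3 points (95% bootstrap interval 20.6 to 42.1), which argues against saturation as the whole cause. In that set the interferon-stimulated genes also rose more (median 4.10 against 2.56). Level and size of the rise were not held alike in a single test. When genes were chosen and measured on separate gardiquimod arrays the difference was 23.3 points (16.3 to 35). That choice kept 48 and 35 genes, as many as the choice on all arrays. It therefore hardly tests an effect of sharing the gardiquimod arrays, which stays open. The unstimulated arrays were still shared by both steps. A larger initial rise is argued against by 20.6 points (14.9 to 27.4) in 23 pairs of genes whose rises lay within log2 0.25. Pairs were used because among genes that rose 2- to 16-fold (24.1 points) the interferon-stimulated genes still rose more (median 2.86 against 1.86). These intervals cover the choice of genes, not the spread between arrays. The share differed in the same direction in both donors (28.6 and 24.7 points), but the planned list-score test, which takes log2 changes of all members, raised or not, detected no difference (0.20 from cytokines and 0.08 from NF-kB genes, exact permutation p = 0.095 and 0.385) and was negative in one donor (-0.05 and -0.17). An effect of the compound that differs between the lists remains a hypothesis, found and examined on the same data, and its cause stays open.

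CYP1B1 rose with BMS-986126 above its unstimulated level. A faulty probe set is argued against by its other probe sets, which had a median change of 3.12 and of which 3 of 4 were called. A mere return from the fall with gardiquimod is argued against by the level with the compound, 2.06 above unstimulated. Activation of the aryl hydrocarbon receptor is a candidate explanation that these arrays cannot decide: of 6 other measured targets 1, AHRR, rose in each donor alone, and 8.46% of 10000 random lists matched on level had at least as many. The absence of a compound-only group leaves open whether the rise needs gardiquimod.

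The change with the compound differed between the donors, with 435 genes called for the difference. RNA quality may contribute and cannot be told apart: the 3' to 5' change of control genes differed between donors by 0.0813 for GAPDH (exact permutation p = 0.04) and by 0.0167 for beta-actin (exact permutation p = 0.935), and how far such a shift moves other genes was not measured. A loss of monocytes or dendritic cells in one donor also stays open: the score of monocyte markers differed by 0.235 ± 0.04 (adjusted p = 0.000553), that of conventional dendritic cell markers by 0.19 ± 0.07 (adjusted p = 0.0413) and that of plasmacytoid markers by 0.05 ± 0.05, which was not called. The members of these lists moved in both directions with the compound, so the scores do not measure the number of cells. No characteristic of the donors was used, and other biological explanations were not tested.

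Other divisions of the same arrays into groups of the same size were tried for each comparison, 100 including the real one. Only the real one gave as many genes (1 of 100 in each comparison, the smallest share this number of divisions can give). This argues against a chance division of these wells but does not exclude it. The other divisions mix the conditions, so a true difference widens their spread and lowers their counts. Nothing follows from them for other donors. The real counts were 7098, 3112 and 5504, and the highest of the other divisions gave 3344, 1062 and 2698.

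Single arrays stood apart from the other 5 of their condition in 24 of 723 groups examined (3.32%). Chance gives about 1 in 20 for 6 alike arrays, but each group holds 3 arrays of each donor, and a difference between donors widens the range and can hide a lone array. The score of glucocorticoid response genes was 7.056 on 1 array with the compound. In unstimulated cells the lone log2 values were 3.014 for CCNA2, 3.353 for FSD1L, 6.554 for GCLM, 5.489 for HMGCS1, 7.618 for RFX5, 11.32 for TSC22D3, 6.996 for TXNRD1, 4.51 for USP18 and 2.489 for XCL1. With gardiquimod they were 3.254 for CCNA2, 7.981 for CD5, 3.308 for CLEC10A, 7.373 for DUSP10, 9.355 for FOS, 5.087 for MMP9, 10.98 for MNDA and 9.178 for SOCS1. With the compound they were 8.81 for FKBP5, 4.385 for FSD1L, 8.678 for IDI1, 5.414 for IL1R1, 3.834 for PDE2A and 10.92 for RPL7.

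The 2 donors differed in the change of 241 genes with gardiquimod, of 435 with the compound against gardiquimod and of 562 with the compound against unstimulated, by limma's interaction test. List scores differed between donors, given as absolute differences on the log2 scale. With gardiquimod the differences were 3.634 for interferon genes (adjusted p = 1.06e-12), 0.3466 for inflammatory cytokines, 0.1294 for immediate-early genes, 0.1754 for HLA class II machinery, 0.1733 for glycolysis, 0.203 for NRF2 targets, 0.1591 for the unfolded protein response, 0.3635 for glucocorticoid response genes, 0.326 for monocyte markers and 0.1088 for T cell markers. With the compound against gardiquimod they were 0.4475 for interferon-stimulated genes, 0.6619 for interferon-gamma response genes, 0.2026 for immediate-early genes, 0.3776 for costimulation genes, 0.1726 for glycolysis, 0.2269 for aryl hydrocarbon receptor targets, 0.289 for the unfolded protein response, 0.2254 for heat shock genes, 0.2352 for monocyte markers and 0.19 for conventional dendritic cell markers. With the compound against unstimulated they were 0.315 for interferon-stimulated genes, 3.379 for interferon genes, 0.654 for interferon-gamma response genes, 0.1195 for the Toll-like receptor pathway, 0.4479 for costimulation genes, 0.2688 for aryl hydrocarbon receptor targets, 0.2476 for NRF2 targets and 0.2757 for glucocorticoid response genes.

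Probe sets without a single gene name (4040) took no part in the comparisons. Of these, 150 changed at least 2-fold with gardiquimod, 120 higher and 30 lower, and 19 changed at least 2-fold with the compound against gardiquimod, 7 higher and 12 lower.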

How the results depend on the processing

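Every alternative setting was fixed beforehand, and where a value changed the cause was not tested unless the setting itself shows it. Of the called genes named by the rule, 98 of 132 with gardiquimod, 30 of 127 with the compound against gardiquimod and 68 of 115 with the compound against unstimulated kept their call under every alternative. Median centring and renewed quantile normalisation turned no direction of a named gene.

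With the 2 donor means as replicates, which leaves fewer values per group, the compound against gardiquimod gave 243 genes higher and 246 lower (88 lower at 2-fold, and 3286 genes at an unadjusted p under 0.05), and the compound against unstimulated gave 967 and 2152. Without the donor term, which puts the donors' difference into the spread, the compound gave 1009 and 858. In the test against a 1.5-fold change, a stricter criterion, the counts were 756 higher and 528 lower for gardiquimod, 33 and 92 for the compound against gardiquimod (85 lower at 2-fold) and 456 and 193 for the compound against unstimulated.

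Each donor alone leaves fewer arrays. In one donor the compound against gardiquimod gave 678 higher and 630 lower (87 lower at 2-fold), 35.4% of risen genes were lowered and 38.1% of fallen genes raised, and 258 genes were at least 2-fold lower than unstimulated. In that donor HMOX1 changed with gardiquimod by -0.41 against its overall rise, and ISG15 with the compound by 0.12. In the other donor 67 genes were at least 2-fold higher and 219 lower with the compound, the compound against unstimulated gave 981 and 1697 (93 lower at 2-fold), MYD88 changed by -0.0843, and the remaining shares were 56.7% of the rise and 52.7% of the fall. The score of interferon-stimulated genes rose with gardiquimod more than that of cytokines by 2.16 and 2.64 and more than that of NF-kB genes by 2.45 and 2.84 in the donors, where an exact test cannot reach p = 0.05. With the compound these differences were -0.0485 and -0.17 in the other donor.

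With the mean of a gene's probe sets, 194 genes were at least 2-fold lower with gardiquimod, 18 at least 2-fold higher with the compound and 103 at least 2-fold lower with the compound than unstimulated. MYD88 then changed by -0.0694 with the compound, and 1 list was called down with gardiquimod. With the probe set of the largest spread, MCM6 changed by 0.061 with gardiquimod, MYD88 by -0.17 and RPL18 by -0.18 with the compound.

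With the estimated correlation, 0 lists were called up and 1 down for the compound against gardiquimod, and 0 down for the compound against unstimulated. A filter on dim probe sets left 2 lists called up for the compound against gardiquimod.

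Leaving out each array in turn gave 3 to 7 lists called up for the compound against gardiquimod, with 7 without gardiquimod replicate 2. ISG15 then changed by -0.0591 to 0.0165 and MYD88 by -0.0294 to 0.0298, and neither was called. The remaining share of the rise lay between 69.0 and 74.0%, and that of the fall between 65.1 and 70.2%.

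With the replicate as a fixed block, 7109, 2979 and 5422 genes were called. No count moved by 1.5 times and none of the called lists lost its call. The call was lost for 3, 5 and 0 named genes, among them IFNB1 with the compound (adjusted p = 0.0783).

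Signal over background limits the dim genes, among them the interferon genes in unstimulated cells, whose changes may be understated. The call of IFNB1 with the compound ended without gardiquimod replicate 1, 2 or 3 and without compound replicate 4, 5 or 6, at values of -1.46 to -1.30.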

Other observations

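Several genes outside the lists also changed strongly. FFAR2, a receptor for short-chain fatty acids, rose by 6.18 ± 0.19 with gardiquimod (adjusted p = 7.94e-17 by limma), from 4.68 to 10.87, and stood at 9.80 with BMS-986126. The potassium channel genes KCNJ15 and KCNE3 fell (log2 changes of -3.49 ± 0.15 and -2.93 ± 0.13), although another KCNJ15 probe set changed by -0.52, and KCNE3 rose again by 1.57 ± 0.13 with the compound. PDE2A, a phosphodiesterase, fell by 3.29 ± 0.28 on its main probe set and by 0.38 on another.

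Beyond CYP1B1, some genes stood higher with gardiquimod and BMS-986126 than with gardiquimod alone by more than gardiquimod had lowered them. LRRN3 was at 5.53 in unstimulated cells, 5.09 with gardiquimod and 6.87 with the compound, and FUCA1, a lysosomal fucosidase, was at 5.21, 4.37 and 6.06. TIFAB, at 3.21 in unstimulated cells, was at 6.86 with gardiquimod and 4.25 with the compound, and KCTD12 was at 6.63, 10.33 and 7.86.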
